A study of Homo sapiens with 8 samples.

How the data were processed

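Total RNA of K562 and K/VP.5 cells in log phase was made into small RNA libraries with the NEBNext kit, size selected and sequenced from both ends with 75 base reads, per the labels' protocols. Per the same protocols, reads were trimmed with Cutadapt 2.4 and those of 15 to 50 bases were aligned with Bowtie 1.1.2 (seed length 18), first to rRNA and tRNA with 0 seed mismatches, then to mature sequences of miRBase 21 with 1 mismatch and up to 5 alignments per read, and last to unique positions of GRCh38. Samtools and in-house R scripts then counted reads per mature miRNA. The deposited values are expected counts without normalization: 205 of the 868 mature miRNA rows hold fractions, from reads split over several mature sequences, and the authors' counting and annotation of the other 16404 rows, all in whole counts, is not given in the sources used here. A read that differs from its mature sequence can be lost to the miRBase step and be counted in the genome step, so mature counts may be a lower limit for some miRNAs. The protein-coding rows mostly held even numbers (78.5% of nonzero values), and some reads appear under a hairpin and its host gene.

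Mature miRNA values were rounded to whole counts. The plan written before the data were examined had assumed whole counts, and the same test was kept. The sums over mature miRNAs ran from 55033 to 614475. There 1 count is worth 18.2 CPM of the plain total in the shallowest library and 1.63 CPM in the deepest. Library sizes in the test were the sums over the rows that passed the filter, which held 99.8% of the mature counts. Rows were filtered with filterByExpr (minimum count 10, minimum total 15), scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, K/VP.5 against K562, at a Benjamini-Hochberg adjusted p of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. CPM values of single miRNAs and rows are on TMM-scaled library sizes, where 1 count is worth 17.0 CPM in the shallowest library, and pooled CPM are on plain totals. The residual coefficient of variation between libraries was 28.9%. Where a line had 0 counts the fold change is a lower bound against 3 counts over its libraries. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

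The 26 lists of miRNAs were fixed before the data were examined. Those with at least 3 tested members, 16 lists, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and also at an estimated one, and calls adjusted over the list alone were counted beside. Single values per library were compared with exact two-sided permutation tests, which cannot go below p = 0.0286 for 4 against 4. miRNAs were named by a rule fixed beforehand: the 8 largest rises and 8 largest falls among called miRNAs whose libraries do not overlap and that reach 100 CPM in a line, the 10 most abundant, both arms of miR-9, and up to 3 members of each list with the smallest adjusted p. Other names were chosen after their values were seen: miR-370-3p, miR-381-3p, miR-409-3p and miR-543 as the remaining tested members of the 14q32 list, miR-146b-5p and the hairpin rows named in the report, and those in the closing section. Hairpins were located by name in GENCODE 44 on GRCh38, which matched 863 of the 868 mature rows. Figures were drawn with matplotlib 3.10.9.

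The test was tried on simulated data with real means and depths. In 268 simulated rows it called 13 of 29 miRNAs changed 2-fold, 30 of 30 changed 4-fold and 1 of 209 unchanged ones. All simulated rows had the same dispersion, and no library had a profile or GC trend of its own. These rates need not hold for the real libraries. Libraries of a line differed beyond counting noise in every pair, so none is a second copy of another. Repeat libraries of 1 RNA can differ as well, so this does not show separate cultures. Alternatives were RLE, upper-quartile or no scaling, no filter or 10 CPM in 4 samples, no most abundant miRNA, collapsed identical rows, a minimum of 2-fold, DESeq2 1.42.0, limma-voom, the replicate number as a block and each library left out. Thinning and corrections for GC content, by the hairpin arm in the reference, were added after the data were seen. Other small RNA, hairpin and protein-coding rows were tested in the same way, each class on its own, and are used in the closing section. The rows of MIR224 and MIR451A, which hold many more counts than the mature miRNA, are also given beside the mature values.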

Results

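Small RNA libraries were sequenced from K562, a human cell line derived from chronic myelogenous leukemia, and from K/VP.5, a clone of K562 that was selected in etoposide and is kept under repeated exposure to 0.5 µM of the drug. Etoposide poisons DNA topoisomerase II, and the question put to the libraries was which mature miRNAs differ between the resistant clone and its parent. There were 8 libraries, 4 per line. Counts assigned to mature miRNAs came to 55033, 614475, 465298 and 288724 in K562 replicates 1 to 4, and to 332475, 495217, 486139 and 437604 in K/VP.5 replicates 1 to 4. Of the 868 mature miRNAs listed, 253 had enough counts for the test, and these held 99.8% of the mature counts. Nothing in the labels says whether the 4 libraries of a line came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. K562 replicate 1 stood apart from the other libraries of its line. Its log CPM correlated with theirs across miRNAs at r from 0.912 to 0.934, against 0.975 to 0.989 for all other pairs within a line.

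A total of 82 mature miRNAs differed between the lines, with 46 higher and 36 lower in K/VP.5. Of the 253 tested rows 105 held fractions from shared reads and 13 had the same values as another row. The 82 therefore need not all be distinct miRNAs. Among the most raised were miR-504-5p, from 6.86 ± 8.04 CPM in K562 to 198 ± 11.1 CPM in K/VP.5, miR-9-5p, from 51.2 ± 30.2 CPM in K562 to 1020 ± 254 CPM in K/VP.5, and miR-196a-5p, from 57.8 ± 44.5 CPM in K562 to 697 ± 71.9 CPM in K/VP.5 (mean ± SD, n = 4 throughout). The deepest falls were those of miR-625-3p, from 163 ± 62.4 CPM in K562 to 3.87 ± 3.47 CPM in K/VP.5, and of both arms of miR-139. The miR-224 and miR-452 pair fell as well, and miR-452-5p, an abundant miRNA of the parent, dropped from 4849 ± 2085 CPM in K562 to 514 ± 151 CPM in K/VP.5. In all, 68 miRNAs changed by at least 2-fold, 37 upward and 31 downward.

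Among the miRNAs that rose in every K/VP.5 library over every K562 library, and that reached 100 CPM in a line, the 8 largest log2 fold changes (± SE) started with miR-504-5p at 4.34 ± 0.41 (adjusted p = 1.23e-06). Its hairpin lies on chromosome X from 138667711 to 138667793 in GRCh38, in an intron of FGF13. miR-127-3p rose by 3.52 ± 0.34, miR-493-5p by 3.40 ± 0.33 and miR-493-3p by 2.94 ± 0.36. These come from the imprinted 14q32 region, where MIR493 lies at 100869060 to 100869148 and MIR127 at 100882979 to 100883075 of chromosome 14, within MIR493HG. miR-675-5p, which is processed from exonic sequence of the imprinted non-coding RNA H19 (chromosome 11, 1996759 to 1996831), rose by 3.50 ± 0.39, from 16.5 ± 16.4 CPM in K562 to 250 ± 33.1 CPM in K/VP.5. miR-196a-5p, encoded in introns within the HOXB and HOXC clusters, rose by 3.35 ± 0.39, and miR-3681-5p rose by 3.26 ± 0.33. The count of miR-196a-5p includes reads shared with other mature miRNAs.

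**Figure D1:**
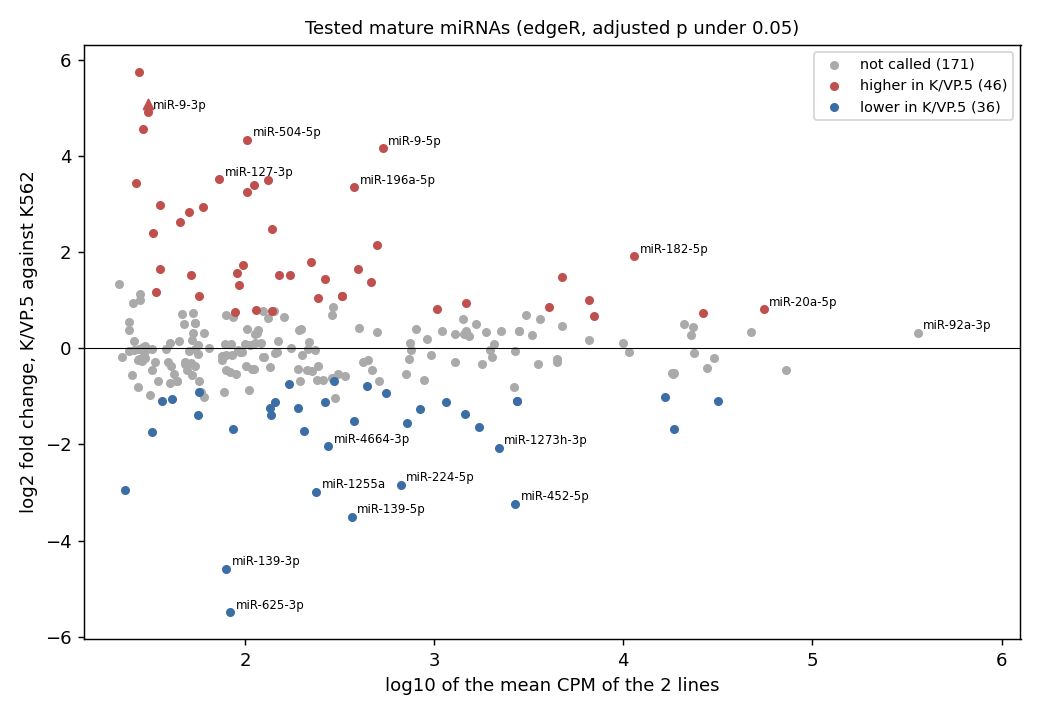
Log2 fold change of each tested mature miRNA (K/VP.5 against K562) against the log10 of its mean CPM in the lines. Red points rose (46), blue points fell (36) and grey points were not called (171), and miR-9-3p, with 0 counts in K562, is drawn at its lower bound with a triangle.

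The 8 largest falls under the same conditions were led by miR-625-3p at -5.49 ± 0.49 (adjusted p = 1.23e-06), from an intron of FUT8 on chromosome 14 (65471102 to 65471186). miR-139-3p fell by 4.59 ± 0.48 on the log2 scale and miR-139-5p by 3.51 ± 0.40, the latter from 674 ± 82.5 CPM in K562 to 57.8 ± 40.4 CPM in K/VP.5. Their hairpin lies in an intron of PDE2A (chromosome 11, 72615063 to 72615130). The log2 fold change of miR-452-5p was -3.24 ± 0.37 and that of miR-224-5p was -2.84 ± 0.34, from 1170 ± 410 CPM in K562 to 165 ± 52.5 CPM in K/VP.5. The row of the hairpin MIR224 held 223091 counts, against 2287 in its mature rows, and its log2 fold change was -3.04. Both hairpins overlap annotated exons of GABRE on chromosome X, MIR224 at 151958578 to 151958658 and MIR452 at 151959628 to 151959712. miR-1255a changed by -2.99 ± 0.36, miR-1273h-3p by -2.07 ± 0.40, from 3544 ± 2218 CPM in K562 to 838 ± 278 CPM in K/VP.5, and miR-4664-3p by -2.04 ± 0.35. These hairpins lie in introns of PPP3CA, PRKCB and FAM83H. Values of miR-625-3p and miR-1255a include shared reads.

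edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment made these calls, and 102 miRNAs had an unadjusted p under 0.05. In 65 of the 82 every library of one line lay outside the range of the other. The 82 were picked on the same counts, so this is no separate support. Of all 253 tested miRNAs 79 were separated, where chance gives 2.86% of unchanged ones. Without K/VP.5 replicate 4 the count of falls was 20 instead of 36, and after thinning all libraries to the depth of K562 replicate 1 there were 17 rises and 17 falls. Removing a trend with GC content moved the median log2 fold change by -0.24 and gave 39 rises and 52 falls, and 47 and 29 when each library's level was kept.

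miR-9 was the pair of arms that the study followed as regulators of topoisomerase IIα, and it was picked with these libraries in hand, so its rise here is not independent evidence. miR-9-5p rose by 4.16 ± 0.37 on the log2 scale (adjusted p = 1.23e-06), and every K/VP.5 library exceeded every K562 library. miR-9-3p had 0 counts in each K562 library and 9, 29, 43 and 26 counts in the K/VP.5 libraries, for 61.1 ± 28.3 CPM. It was at least 30.1-fold higher in K/VP.5 against a floor of 3 counts over the K562 group, with an adjusted p of 3.28e-05. The mature sequences come from 3 hairpins that the counts cannot separate, MIR9-1 on chromosome 1 (156420341 to 156420429), MIR9-2 on chromosome 5 (88666853 to 88666939) and MIR9-3 on chromosome 15 (89368017 to 89368106), each exonic in a long non-coding RNA. Among 7 miRNAs listed beforehand as linked to topoisomerase IIα, 3 were tested. The arms of miR-9 rose and miR-139-5p fell, with the same 3 calls when adjusted over the list alone. The list itself was not called (adjusted p = 0.457).

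**Figure D2:**
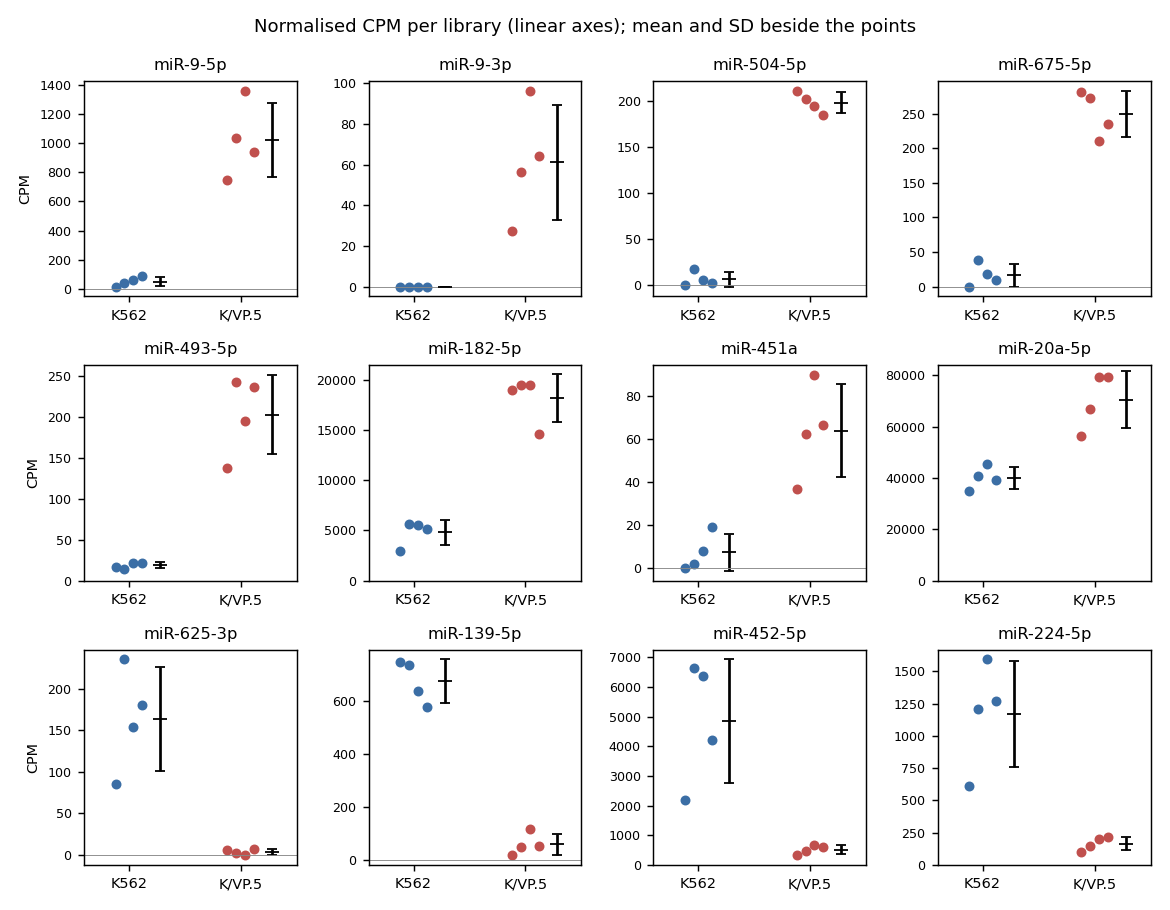
CPM in each library (points, linear axes) of 12 miRNAs in K562 (blue) and K/VP.5 (red), with the mean and SD of the 4 libraries in black. miR-9-3p is at 0 in every K562 library, and miR-182-5p ranges from 14543 to 19500 CPM in K/VP.5.

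The 14q32 list had the smallest adjusted p of the 16 lists tested. All 7 of its tested members rose, and all 7 did when adjusted over the list alone, with a median log2 fold change of 2.94. Besides miR-127-3p and miR-493, they were miR-370-3p, miR-381-3p and miR-543, with log2 fold changes of 2.83, 2.48 and 3.44, and miR-409-3p, which went from 8.45 ± 6.29 CPM in K562 to 56.7 ± 18.4 CPM in K/VP.5. Pooled over the 33 list members in the table, the region gave 122 ± 36.5 in K562 and 931 ± 102 in K/VP.5 CPM (exact permutation p = 0.0286, the smallest that 4 against 4 allows). camera gave an adjusted p of 1.45e-07 with a preset correlation and an adjusted p of 0.2898 with an estimated correlation. No list was called with an estimated correlation.

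**Figure D3:**
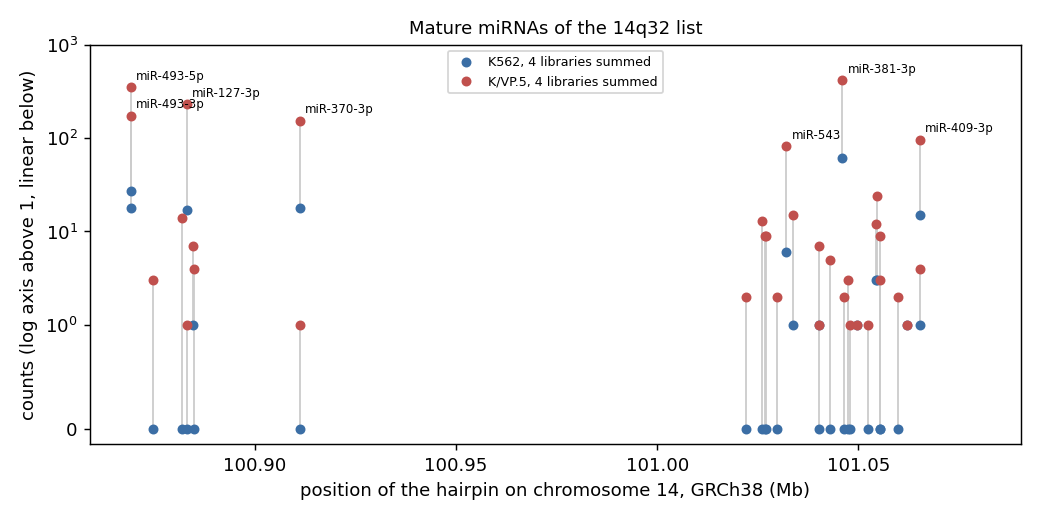
Summed counts of each mature miRNA of the 14q32 list in the 4 K562 libraries (blue) and the 4 K/VP.5 libraries (red), at the position of its hairpin on chromosome 14 in GRCh38. The 7 named miRNAs are those tested, and miR-381-3p has the most counts, 61 in K562 and 414 in K/VP.5.

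The cluster of miR-182, miR-96 and miR-183, transcribed as a unit from chromosome 7, rose as well, with all 3 tested members higher. miR-182-5p went from 4793 ± 1259 CPM in K562 to 18131 ± 2403 CPM in K/VP.5, a log2 fold change of 1.91 ± 0.27 (adjusted p = 3.28e-05). miR-96-5p rose by 1.66 ± 0.28 and miR-183-5p by 1.49 ± 0.27, and the 3 calls stood when adjusted over the list alone. The list's adjusted p was 0.0386 with the preset correlation, and the adjusted p was 0.494 with an estimated correlation. It was 0.0618 without K562 replicate 4, and 0.0616, 0.0593 and 0.0547 without K/VP.5 replicates 1, 2 and 3.

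Some members of 3 clusters, miR-17-92, miR-106a-363 and miR-106b-25, rose modestly. None of these clusters was called as a list, with adjusted p of 0.493, 0.497 and 0.883 in that order. In the miR-17-92 cluster 4 of 10 tested members rose, the same number when adjusted over the list alone: miR-20a-5p from 40133 ± 4309 CPM in K562 to 70435 ± 11148 CPM in K/VP.5, and miR-17-5p, miR-19a-3p and miR-19b-3p by 0.72, 0.82 and 0.93. In the miR-106a-363 cluster 2 of 3 rose, miR-20b-5p by 0.77 and miR-106a-5p by 0.68, while miR-18b-5p had a value of 0.42. In the miR-106b-25 cluster 1 of 5 did, miR-93-5p by 0.85, and miR-25-3p and miR-106b-3p had values of 0.45 and -0.32. Counts over each list alone were again 2 and 1. Members of these clusters share reads. Calls were lost without single libraries, among K562 replicates 2 and 4 and K/VP.5 replicates 2 to 4. There the adjusted p reached 0.0968 for miR-17-5p, 0.0932 for miR-19a-3p, 0.126 for miR-20b-5p, 0.128 for miR-106a-5p, 0.0758 for miR-93-5p and 0.0513 for miR-19b-3p. Without a filter all of these but miR-19b-3p lost their calls. miR-20a-5p kept its call without each library, and its adjusted p was 0.321 after removing the GC trend, 0.0548 with library levels kept and 0.105 without a filter.

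Of 4 tested miRNAs of the red cell lineage 2 were called, both higher, and the list was not called (adjusted p = 0.315, and 0.494 with an estimated correlation). miR-451a, which rises late in erythroid maturation, went from 7.17 ± 8.55 CPM in K562 to 63.8 ± 21.7 CPM in K/VP.5 (log2 fold change 2.98 ± 0.52, adjusted p = 3.38e-04). This rests on 122 mature counts, against 10105 in the row of its hairpin MIR451A, whose log2 fold change was 1.40. Its neighbour miR-144-5p rose by 1.31 ± 0.38, a call that was lost without K562 replicate 2 or K/VP.5 replicate 2 or 4 (adjusted p up to 0.0641). miR-486-3p had a value of 0.62 and was not called, but it was without K562 replicate 1 (adjusted p = 0.0412), with upper-quartile scaling and with either GC correction. Over the list alone 3 of 4 rose. Of the myeloid markers, 5 were tested: miR-223-5p fell by 1.72 and miR-146a-5p by 1.40 on the log2 scale, and miR-342-3p rose by 0.77, a call lost without any of 6 libraries, K562 replicates 2 to 4 and K/VP.5 replicates 1, 3 and 4 (adjusted p up to 0.156), and with DESeq2, limma-voom, a replicate block, no scaling, no filter or each GC correction. The other arm of MIR223, miR-223-3p, was not called (log2 fold change -0.45, adjusted p = 0.232). The row of that hairpin was called lower (-1.36, adjusted p = 9.19e-04). The calls over the list alone were the same 3 in number, and the list's adjusted p was 0.457.

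**Figure D4:**
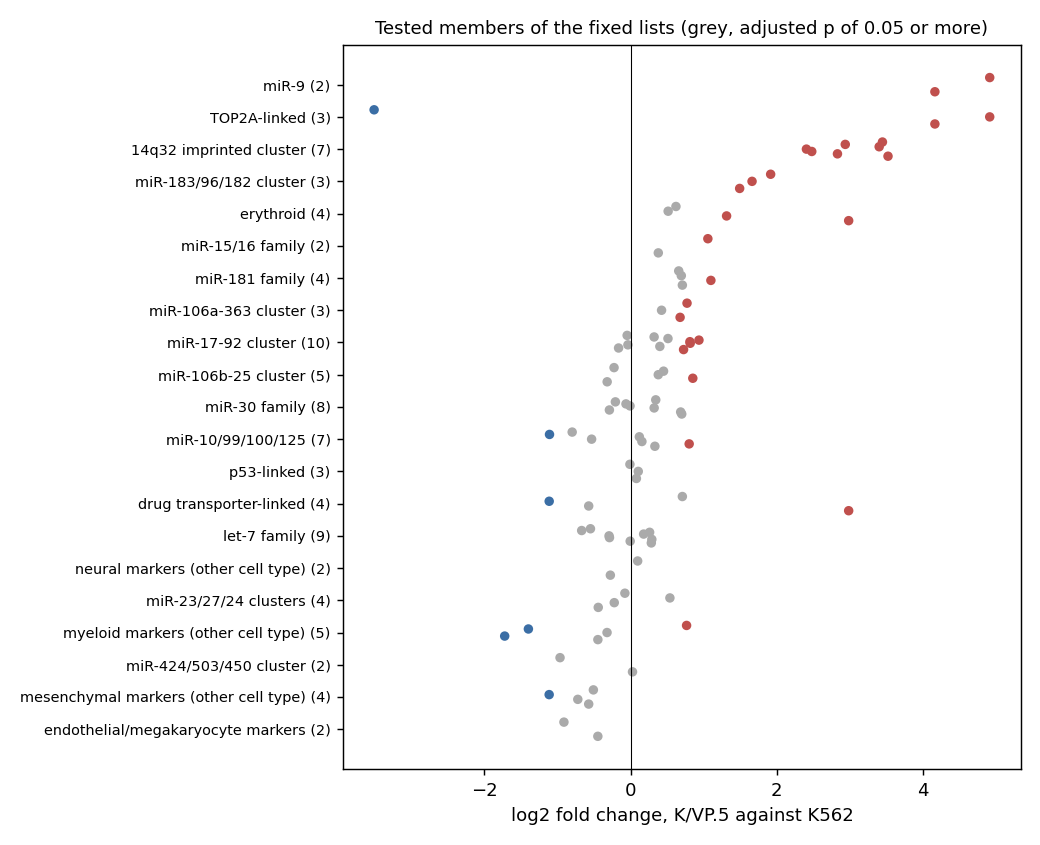
Log2 fold changes (K/VP.5 against K562) of the tested members of each fixed list with at least 2 of them, ordered by the median, with the number tested in parentheses. Red members rose, blue members fell and grey members were not called, and miR-9-3p is drawn at its lower bound.

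In the other lists few miRNAs passed the test. None of the 9 let-7 members was called, 0 over the list alone as well (list adjusted p = 0.883), with let-7i-5p at -0.67 ± 0.26 (adjusted p = 0.0659), miR-98-5p at -0.55 and let-7e-5p at -0.29. All of these 3 were called without K562 replicate 1 (adjusted p of 0.00862, 0.0418 and 0.0294, with let-7e-5p at -0.53), and let-7i-5p also without K/VP.5 replicate 1 and with DESeq2, RLE scaling, thinning, either GC correction or the most abundant miRNA left out. None of the 8 members of the miR-30 family was called either, again 0 over the list alone (list adjusted p = 0.883), among them miR-30c-5p at 0.68, miR-30b-5p at 0.70 and miR-30e-3p at 0.34. Without K562 replicate 3, miR-30b-5p was called at 1.16 (adjusted p = 0.0161) and so was miR-30c-5p (0.0226), the latter also without K562 replicate 1 and with DESeq2, limma-voom or upper-quartile scaling, and both with a replicate block. miR-181b-5p rose from 31.5 ± 22.2 CPM in K562 to 83.3 ± 11.2 CPM in K/VP.5 (adjusted p = 0.0219) as 1 of 4 tested members of its family, and over the list alone 3 did (list adjusted p = 0.457). Its adjusted p was 0.0590 at most without a library, and the call ended without K562 replicate 3 or K/VP.5 replicate 2 or 3. In the list of miR-10, miR-99, miR-100 and miR-125, with 7 tested, miR-99b-3p fell by 1.11 on the log2 scale and miR-10b-5p rose by 0.80. The other arm, miR-99b-5p, was not called (-0.53, adjusted p = 0.126). It held 32915 counts in K562 and 24962 in K/VP.5, against 2309 and 1246 for miR-99b-3p. The row of the hairpin MIR99B was not called either (-0.18, adjusted p = 0.467), so the fall is that of the minor arm. Only the fall of miR-99b-3p was called over the list alone, and the list's adjusted p was 0.883. The adjusted p of miR-10b-5p reached 0.131 without single libraries, K562 replicates 3 and 4 and each K/VP.5 library. Its call was also lost with each GC correction, and that of miR-99b-3p with the one that keeps library levels. miR-16-5p rose by 1.06 ± 0.26 and miR-15b-5p had a value of 0.38. These were the tested members of the miR-15/16 family, and over the list alone 1 was called.

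Neither p53-linked miRNAs (0 of 3 called, miR-192-5p at 0.08, miR-194-5p at 0.11 and miR-215-5p at -0.01) nor the miR-23/27/24 clusters (0 of 4, miR-27a-5p at -0.44, miR-24-3p at -0.22, miR-27b-3p at 0.54) held a call. Among 4 tested miRNAs linked to drug transporters, miR-451a rose, miR-328-3p fell by 1.11 on the log2 scale, and miR-145-5p had a value of -0.57. The fall of miR-328-3p was lost without K562 replicate 1 or 2 or K/VP.5 replicate 1, 2 or 4, with adjusted p from 0.0558 without K562 replicate 1 upward, and a log2 fold change of -0.70 without K562 replicate 1. It was also lost with RLE scaling or without the most abundant miRNA (both 0.0590), with limma-voom (0.0559), after thinning (0.0913) and with each GC correction (0.0615, and 0.128 with library levels kept, at log2 fold changes of -0.80 and -0.53). The counts over these 3 lists alone were 0, 0 and 2, and their adjusted p were 0.963, 0.883 and 0.900. Members of the cluster of miR-424, miR-503 and miR-450 (0 of 2, miR-450b-5p at -0.96 and miR-503-5p at 0.03) and of the miR-29 family (0 of 1, miR-29a-3p at 0.14) were not called, over all miRNAs or over the list alone. miR-450b-5p was called without K562 replicate 1 (adjusted p = 0.0290) and with either GC correction, and its value was -0.56 without K562 replicate 3. miR-221 had 2 counts in K562 and 17 in K/VP.5 and was not tested. The primate-specific C19 cluster had 0 counts in K562 and 16 counts in K/VP.5, or 9.14 CPM, at least 4.33-fold higher.

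Of 4 mesenchymal markers tested, miR-199b-5p fell by 1.11 on the log2 scale, miR-145-5p and miR-145-3p had values of -0.57 and -0.72, and 1 was called over the list alone (list adjusted p = 0.315). None of the 2 endothelial and megakaryocytic markers was called, miR-126-3p at -0.45 ± 0.44 and miR-126-5p at -0.91 ± 0.50, nor were the epithelial miR-200c-3p at 0.40 or the neural miR-128-3p at -0.28 and miR-7-5p at 0.10, over all miRNAs or over each list alone. With each library left out in turn, values ran from -0.88 to -0.27 for miR-126-3p (lowest without K/VP.5 replicate 3, highest without K562 replicate 3), -1.36 to -0.57 for miR-126-5p (the same libraries) and 0.21 to 0.75 for miR-200c-3p (lowest without K562 replicate 3, highest without K562 replicate 2), none of them called. The liver and muscle markers had 6 counts in K562 and 40 in K/VP.5, nearly all miR-1-3p, and were not tested.

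Among the mature miRNA rows, miR-92a-3p was the most abundant in both lines. Hairpin rows, some of them large, are not part of this ranking. miR-92a-3p took 32.9 ± 5.05% of the mature counts in K562 and 38.5 ± 3.41% in K/VP.5 (exact permutation p = 0.114, two-sided). By the mean over all 8 libraries it was followed by miR-126-3p, miR-20a-5p, miR-10a-5p, miR-941, miR-3529-3p, miR-378a-3p, miR-17-5p, miR-148a-3p and miR-25-3p. The hairpin of miR-3529-3p (chromosome 15, 88611847 to 88611924) lies within MIR7-2 (88611825 to 88611934), on the opposite strand. Whether its counts include reads of miR-7 was not tested. The order differs between libraries. miR-146b-5p exceeded miR-17-5p, miR-148a-3p and miR-25-3p in K562 replicates 2 to 4. miR-20a-5p exceeded miR-126-3p in K562 replicate 1 and in K/VP.5 replicates 1, 2 and 4. Of these 10, miR-20a-5p and miR-17-5p rose and miR-941 fell by 1.09 on the log2 scale (adjusted p = 0.0393). The value of miR-941 was -0.51 without K562 replicate 1 (adjusted p = 0.122), and the call was also lost without K562 replicate 2 or K/VP.5 replicate 2, 3 or 4 (adjusted p up to 0.130), and with RLE scaling or without the most abundant miRNA (both 0.0590), with limma-voom (0.0939), after thinning (0.0506) and with each GC correction (0.0915, and 0.247 with library levels kept, at log2 fold changes of -0.74 and -0.41). miR-92a-3p had a log2 fold change of 0.32 ± 0.20, miR-10a-5p of 0.33, miR-3529-3p of -0.20, miR-378a-3p of -0.41 and miR-148a-3p of -0.10. miR-378a-3p was called without K562 replicate 1 (adjusted p = 0.0406) and with the first GC correction. The 10 most abundant miRNAs of each library together held 70.0 ± 1.32% in K562 and 72.3 ± 1.62% in K/VP.5 (exact p = 0.114). At equal depth 315 ± 8.13 mature miRNAs were detected in K562 and 321 ± 4.65 in K/VP.5 (exact p = 0.200).

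Mature miRNAs made up 20.96 ± 1.60% of all counts in the K562 libraries and 32.8 ± 2.64% in K/VP.5 (exact permutation p = 0.0286, the smallest possible). Rows of other genes count some reads more than once, so the percentage is a property of the table and not a share of molecules.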

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

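The tests here of reads shared between miRNAs, of a mesenchymal cell type, of the whole region and of the splits for the 14q32 list were chosen after the result was seen, and the others before. Of 160 groups of 4 libraries, 9 held a library far from the other 3 by Dixon's test, about what chance gives (1 in 20). In K562 replicate 1 rRNA rows stood at 0.859%, against 0.0455 to 0.0738% in the others. In that library miR-3681-5p was at 0 CPM, against 19.7 to 22.1 CPM in the others of its line, where 1 count in it is worth 17.0 CPM on the same TMM scale. Also in K562 replicate 1, miR-25-3p was at 15241 CPM, against 20644 to 21391 CPM in the others, and miR-30e-3p was at 1069 CPM, against 1811 to 1911. In K/VP.5 replicate 1, miR-941 was at 28109 CPM, against 16579 to 18246 CPM in the others, miR-19b-3p at 1386 CPM, against 2097 to 2152 CPM in the others, and miR-181a-2-3p at 288 CPM, against 165 to 181 CPM in the others. In K/VP.5 replicate 4, miR-27b-3p was at 56.7 CPM, against 22.4 to 24.5 CPM in the others, and miR-182-5p at 14543 CPM, against 19002 to 19500 CPM in the others.

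K562 replicate 1 was both the shallowest library and the one least like its line. When the other K562 libraries were thinned to its total in 100 draws each, their lowest correlation with the rest was 0.946, above the highest of K562 replicate 1, 0.933, which argues against low depth alone. A bias by base composition stays open: its deviation from the other K562 libraries followed the GC content of the hairpin arm across 252 miRNAs with Spearman's rho of 0.337, past the bound of 0.3 set beforehand. Trends as strong occurred in libraries that did not stand apart, up to an absolute rho of 0.502, so such a trend may be part of the difference without setting it apart. No biological explanation was tested.

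snoRNA rows of the 14q32 region, outside the mature miRNAs, were 9.75 times higher in K/VP.5. Pooled over 24 rows they gave 52.2 ± 40.9 in K562 and 509 ± 124 in K/VP.5 CPM over all snoRNA counts, from 36 and 255 counts. This goes with the rise of the 14q32 miRNAs, for which the tables argue against several technical sources. Without the shallow K562 replicate 1 the adjusted p of the list was 1.76e-06, the 6 tested members without shared reads had a median log2 fold change of 3.17, and pooled mesenchymal markers other than miR-21-5p changed by -319 CPM, which argues against cells of that type. Of the 35 splits of the 8 libraries, 1, the real one, gave an adjusted p as small (1.45e-07, next lowest 3.39e-04) at the preset correlation. The next lowest also passed. It came from a mixed split that exchanged 1 library of each line and so keeps part of the line difference. Splits with 2 libraries of each line on both sides had adjusted p of 0.431 or more. A share of 1 in 35 is the smallest possible. Chance is therefore not excluded, and at an estimated correlation the list was not called (adjusted p = 0.2898). A higher output of the whole region, as a hypothesis, is consistent with the snoRNA rows (exact p = 0.0286), and a difference already present in the cell that founded the clone, or gained in culture, stays untested.

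The MIR577 hairpin row held 0 counts in K562 and 270 in K/VP.5. The row of HBE1, the embryonic ε-globin gene, had a log2 fold change of 2.93 (SE 0.56, adjusted p = 0.00956) over the protein-coding rows. It held 0, 7, 1 and 2 counts in the K562 libraries and 16, 13, 30 and 15 in the K/VP.5 libraries. These are short reads of small RNA libraries, so the level of the mRNA was not measured.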

How the results depend on the processing

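Thinning, both GC corrections and all settings of the other rows were chosen after the data were seen. RLE, upper-quartile or no scaling, both filters, DESeq2, limma-voom, collapsed rows, a 2-fold minimum and leaving out the most abundant miRNA gave between 68 and 85 changed miRNAs, and no main call changed sign in any setting with a fit of its own. miR-9-5p and miR-9-3p kept their calls in each setting that tested them. Of 1419 values of single named miRNAs and settings, 1296 stayed on their side of the threshold, 92 lost a call and 31 gained one (let-7i-5p 8, miR-30c-5p 6, miR-486-3p 4, miR-450b-5p 3, miR-30b-5p and miR-378a-3p 2, and let-7e-5p, miR-98-5p, miR-145-3p, miR-145-5p, miR-181a-2-3p and miR-25-3p 1), and 25 of 39 named calls were lost in none. Thinned to the shallowest library, 112 miRNAs were tested and 34 changed, 17 up and 17 down, with 1 list called, as fewer counts leave fewer rows. The lists called were 4 without a filter and 0 with an estimated correlation (adjusted p 0.2898 for 14q32 and 0.494 for the miR-182 cluster), and the cause was not tested. A GC trend correction first called 91 (39 up, 52 down) with a median shift of -0.24. Because it also moved library levels, a second version that keeps them was added after that result had been seen. It called 76 (47 up, 29 down) with a shift of -0.09 and 4 lists. Both end the calls of miR-17-5p, miR-20a-5p, miR-20b-5p, miR-106a-5p, miR-10b-5p, miR-342-3p, miR-328-3p and miR-941, the first alone those of miR-19a-3p, miR-19b-3p and miR-144-5p, and the second alone that of miR-99b-3p. These fold changes came closer to 0, that of miR-941 from -1.09 to -0.74 and -0.41. Which is nearer the truth was not tested. Leaving out each library gave 58 to 97 changed, 37 to 54 up and 20 to 43 down, 1 to 2 lists, and adjusted p of 0.0133 to 0.0618 for the miR-182 cluster and 4.98e-08 to 3.41e-06 for 14q32. With the replicate number as a block 84 changed (51 up, 33 down). The labels do not say whether the numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.22, -0.25, 0.16 and -0.01, which are too few values to settle it. The top-10 share and the number detected stayed without a call in each alternative. Changed rows of small RNAs other than miRNAs were 23 (3 higher and 20 lower), 20 without scaling (12 higher and 8 lower), 12 with RLE, 42 without a filter and 7 to 37 without a library. Changed hairpin rows were 46 (26 higher and 20 lower), 101 without scaling (96 higher and 5 lower) and 74 without K562 replicate 1. Depth limits miRNAs of low abundance: 1 count in K562 replicate 1 is worth 18.2 CPM of its plain total.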

Other observations

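The tests of neighbouring hairpins were chosen after the result was seen, and the counts of splits here before. All names in this part were chosen after their values were seen. Among 291 rows of small RNAs other than miRNAs, 3 were higher and 20 lower in K/VP.5 (edgeR). The called rows are not all distinct RNAs, as VTRNA2-1 and SNORA76C each appear under a pair of gene IDs, the rows of SNORA76C with identical counts. The balance depends on the scaling and on K562 replicate 1: 12 higher and 8 lower without scaling, and 17 higher and 20 lower without that library. VTRNA2-1, a vault-related RNA, fell from 1717 ± 302 CPM in K562 to 458 ± 63.9 CPM in K/VP.5 (log2 fold change -1.91 ± 0.22, adjusted p = 1.88e-04). SCARNA2 changed by -1.92 ± 0.35, from 16022 ± 9828 CPM in K562 to 4232 ± 1363 CPM in K/VP.5. K562 replicate 1, the shallowest library, held 1510 SCARNA2 counts, against 3448, 1162 and 1063 in replicates 2 to 4. The K562 mean is thus raised by that library. Of the snoRNA rows 16 were lower, among them SNORD104 at -0.86 ± 0.13 and SNORD61 at -0.99 ± 0.17, and 2 were higher, SNORD121A at 1.27 ± 0.31 and SNORD101 at 0.87 ± 0.22. The mitochondrial phenylalanine tRNA MT-TF rose by 0.98 ± 0.25. CPM here are over the counts of these classes. Without K/VP.5 replicate 2 or 4 the number of calls was 7, and without K562 replicate 2 it was 11, each time with 0 higher. The rises of SNORD121A, SNORD101 and MT-TF were thus not called there. Without K562 replicate 1 the number was 37.

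Several miRNAs outside the lists moved as well. miR-372-3p rose from 0.459 ± 0.919 CPM in K562 to 54.8 ± 26.6 CPM in K/VP.5, miR-383-5p from 1.41 ± 1.77 CPM in K562 to 56.6 ± 21.3 CPM in K/VP.5 and miR-375 from 173 ± 76.3 CPM in K562 to 823 ± 319 CPM in K/VP.5. On the short arm of chromosome X, rises were called for miR-502-3p at 1.80 ± 0.24, miR-362-5p at 1.54 ± 0.26 and miR-532-5p at 1.01 ± 0.25. Their group of 10 mature rows, put together after these rises were seen and so no test of them, had a pooled level of 5045 ± 511 in K562 and 10108 ± 1943 in K/VP.5 CPM. miR-146b-5p fell from 28341 ± 11369 CPM in K562 to 8888 ± 1048 CPM in K/VP.5. Among 290 protein-coding rows 5 were called: RTL1 (3.33 ± 0.43), which overlaps 14q32 hairpins, HBE1 and TMEM25 (1.27 ± 0.27) were higher, and GABRE (-2.90 ± 0.43), which holds MIR224 and MIR452, and USMG5 (-1.23 ± 0.21) were lower. Since some reads appear under a hairpin and its host gene, such rows may count miRNA reads again. They are no measure of the mRNAs.

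Hairpin rows gave 46 calls in 185 rows, 26 higher and 20 lower. They may hold reads that reached the genome step, but how they were counted is not given. Without scaling beyond the total there were 96 higher and 5 lower, so the balance depends on the scaling, and without K562 replicate 1 there were 37 higher and 37 lower. In 46 called mature miRNAs with a tested hairpin row, the hairpin row had the same sign in 46, and 35 were called in both. Both kinds of row come from the same libraries, so they are no independent replicate. For some miRNAs the hairpin row holds most counts: MIR21 had 1240911 counts against 58624 in its mature rows, MIR146B 1672537 against 64208, MIR224 223091 against 2287, MIR223 25299 against 1439, MIR192 15775 against 267 and MIR451A 10105 against 122, so their mature CPM may stand for a small part of the reads. Of 88 hairpins with 1000 counts or more, the hairpin row was the larger in 45.

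Other splits of the 8 libraries bear on chance. Of the 35 splits, 1, the real one, gave as many changed mature miRNAs (82, highest other 0). The same held for changed rows of other small RNAs (23, highest other 0) and changed hairpin rows (46, highest other 0). These calls went with the line among these libraries, at 1 in 35, the smallest share possible. Chance differences between cultures were not tested. The number of lists called did not set the real split apart: 11 of the 35 splits gave 2 or more, up to 4. Besides the real one, these all exchanged 1 library of each line and so keep part of the line difference. Splits with 2 libraries of each line on both sides gave at most 1 list. The count of lists therefore cannot decide on chance.

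A hypothesis is that miRNAs of one locus change together. Over 20 pairs of hairpins within 10 kb of each other, among 115 single-copy hairpins by their arms without shared reads, the fold changes correlated at 0.884 across pairs, against a 95th percentile of 0.318 over 10000 random placements, and 17 of 20 pairs had the same sign. This leaves out arms with shared reads, among them the called miR-17-5p and miR-93-5p. With every tested arm it was 0.859 over 57 pairs (95th percentile 0.189), 45 of them of the same sign. Some of these pairs are alike by construction: the value of MIR374C, 1.08, equals that of miR-374b-5p, an arm of MIR374B. Random placements do not reproduce this, so the version with every tested arm adds no support. Pairs share hairpins and are not independent. Changes at the level of transcription or gene dosage may lie behind this, and these data do not tell them apart.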
